A study of Mus musculus with 6 samples.

How the data were processed

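Single-cell RNA was measured in injured quadriceps of mice whose endothelial cells can be marked with a red reporter (a Cdh5-driven, tamoxifen-dependent recombinase and a tdTomato reporter). Per the labels, 3 mice received clodronate liposomes into a vein (CLL), which partly ablate circulating monocytes, and 3 received liposomes filled with buffer (SHAM). The liposomes were given 1 day before and 2 days after a cardiotoxin injury, and the muscles were taken 5 days after it. Per the labels' protocols the muscle was digested with dispase and collagenase, red cells were lysed, debris was removed over Ficoll, and libraries were made with the Chromium Single Cell 3' kit, version 3.1. Each library comes from its own mouse, per the labels. Doses, sex and age of the mice, tamoxifen timing, and the days and runs of sequencing are not given in the sources used here.

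The deposited unit is the raw count: a matrix of unique molecular identifiers (UMIs) per gene and barcode for each of the 6 libraries. The matrices were made with Cell Ranger 6.1.2, per the file headers, and aligned to genome build mm10, per the submitters' processing notes. The step that selected the deposited barcodes is not given in the sources used here; none holds fewer than 500 UMIs. The files list 32286 features, 1 of them an added reporter sequence named Tomato. Of the gene identifiers, 32158 matched the reference table of names. A total of 78 features shared their symbol with another. The copy with most UMIs kept the symbol, and the others were told apart by identifier.

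The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Barcodes with at least 300 detected genes and at most 15% mitochondrial UMIs were kept. Scrublet scores were computed per library, and the highest-scoring barcodes were removed as doublets at 0.8% per 1000 barcodes deposited, which took 7032 barcodes, from 1.66% in SHAM replicate 2 to 20.02% in SHAM replicate 1. Of 60282 barcodes, 46685 were kept.

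Kept cells of all 6 libraries were scaled to equal totals, log-transformed, and clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1, without batch integration. Markers were not withheld from clustering. Of the 27 clusters, 18 were named from 17 fixed marker lists and merged into 9 classes. Class names carry "-like" because they rest on transcripts alone. A cluster took a name when at least 3 of the list's genes were each detected in at least 10% of its cells and their mean log2 fold over the other cells was at least 0.5. It also needed at least 20 cells, no equally strong second list, and no lead by ribosomal-RNA-overlapping or mitochondrial transcripts. The exact form of this rule, and the merging of fibroblast and tenocyte lists into 1 class, were set after the clusters had been seen. No cluster was named T/NK-like or neutrophil-like; cluster 20, led by S100a9, S100a8, Gzma and Nkg7, held both kinds of markers and served only as a background class.

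The mouse was the replicate in every test. Class shares were compared with a two-sided exact permutation test on the 6 library values, with Benjamini-Hochberg adjustment over the 9 classes; with 3 against 3 libraries this test cannot go below p = 0.10. For expression, raw counts were summed per library over the cells of a class. A class was tested when every library held at least 20 of its cells. Sums were tested with edgeR's quasi-likelihood test after TMM scaling and filterByExpr, with group as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are log2 of CLL over SHAM with their standard errors (SE); CPM, counts scaled to library size, are given as mean ± SD of 3 libraries. Where every library of a group held 0 counts, the fold is a lower bound against 3 counts over the group. A class-by-treatment interaction between endothelial-like and fibroblast/tenocyte-like sums was tested in edgeR with the library as a block.

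A set of 24 gene lists was fixed beforehand and tested with camera at a preset correlation of 0.01, adjusted over the lists within a class, for lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. For each list, genes past the threshold were counted over all genes tested and again "adjusted over the list alone".

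The genes named were picked by rule. Up to 8 genes per direction with the largest fold were taken among those past the threshold, with no overlap between groups and a mean of at least 20 CPM, leaving out markers of other classes and mitochondrial, ribosomal, haemoglobin and unnamed genes. Up to 4 members with the smallest p of each list discussed were added, and a fixed set per class whatever their p. In endothelial-like cells that set was Pecam1, Cdh5, Acta2, Tagln, Vim, Fn1, Col1a1, Col3a1, Snai1 and Tgfb1, and in macrophage/monocyte-like cells Adgre1, Csf1r, Ccr2, Ly6c2, Mrc1 and Gpnmb. In fibroblast/tenocyte-like cells it was Pdgfra, Col1a1, Postn, Csf1 and Ccl2, and in myogenic-like cells Pax7, Myod1, Myog, Mymk and Myh3. One result of the endothelial-like fit, on a gene picked by this rule, is not reported here. The tests, markers, lists, naming of genes and 93 alternatives were written before the data were examined; 11 alternatives were added afterwards.

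The share of endothelial-like cells with mesenchymal transcripts was computed after drawing each cell down to 1000 UMIs and leaving out shallower cells. A cell counted when at least 2 of Col1a1, Col1a2, Col3a1, Dcn, Acta2, Tagln, Fn1 and Postn had a UMI. Classes taken to lack most of these genes gave the background. Fn1 is also on the fixed list of infiltrating monocyte genes, so part of the macrophage/monocyte-like background may be the cells' own expression.

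Groups carry the same replicate numbers in the labels, so same-number libraries were checked for shared deviations from their group means. In endothelial-like sums the correlations across genes were 0.169, 0.304 and 0.159, all over 0.1, so there the numbers were treated as pairs in a blocked fit beside the unblocked design. In the other classes and in all cells summed at least 1 pair was below 0.1. The labels give no shared litter or day, so the source of this pairing is not given in the sources used here. The correlations come from the same counts that the blocked fit tests, and other classes of the same mice did not show them. The pairing is therefore not established, and the blocked fit is exploratory.

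The gene tests, list tests and interaction were checked on simulated counts drawn from the libraries' own means and sizes with 200 genes changed. The exact permutation tests of shares were not simulated. At 4-fold, edgeR recovered 82.8% of the changed genes in the endothelial-like simulation over 8716 genes and 89.4% in the macrophage/monocyte-like one over 11516 genes. It recovered 93.9% in the fibroblast/tenocyte-like one over 14163 genes and all in the myogenic-like one over 10963 genes. At 2-fold the endothelial-like simulation gave 20.9% and at 1.5-fold 4.62%. The interaction simulation was the weakest, with 68.2% recovered at 4-fold, 11.9% at 2-fold and 0% at 1.5-fold. Camera found the planted list in each class, also with an estimated correlation, and called 1 other list, in fibroblast/tenocyte-like sums. Simulated genes were drawn independently of each other, so this could not show how often camera calls lists of correlated genes falsely. Of edgeR's calls at an adjusted p under 0.05, 5.41% were false in the endothelial-like, 10.4% in the macrophage/monocyte-like, 10.00% in the fibroblast/tenocyte-like, 12.1% in the myogenic-like and 10.8% in the all-cell simulation. In that of the interaction 10.2% were false, so beyond endothelial-like cells the false share was about double the nominal one.

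Alternatives changed the cell filters, doublet removal, resolution, seed, joint clustering, scaling, the filter on low counts, the test, the depth of the sums, the replicate block and the libraries, each in turn. The deposited barcode and feature tables were read only for names. Empty droplets and reads were not among the files used here, so free RNA was not subtracted. A first run had mixed clusterings made before and after a change to the loading step. Its values were discarded and everything was recomputed from the raw counts. The rule that names clusters had been written after clusters of that first run were seen. The lists to discuss, the added lists and the tests of explanations had been written after its gene results were seen too, as had some of the added alternatives.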

Results

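Injured quadriceps muscle was profiled cell by cell in 6 mice, 5 days after cardiotoxin. In 3 mice monocytes were partly ablated by clodronate liposomes (CLL), and 3 received buffer liposomes (SHAM). Total counts were 64325026, 58625420 and 75130565 UMIs in CLL replicates 1 to 3 and 94841003, 23873416 and 32134578 in SHAM replicates 1 to 3. Kept cells numbered 3549, 10148 and 5630 in CLL and 19346, 1848 and 6164 in SHAM. Median UMIs per kept cell were 13820, 1624 and 9145 in CLL and 2760, 9383 and 879 in SHAM. Clusters led by ribosomal-RNA-overlapping or mitochondrial transcripts were left unnamed. They held 55.7% of cells in CLL replicate 2 and 81.5% in SHAM replicate 3, but 9.74% to 14.4% in the other libraries.

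Which cells made up the regenerating muscle with and without partial ablation of monocytes was the first question. Endothelial-like cells, which line vessels and carried Cdh5, Pecam1 and Kdr, were 1.37 ± 0.519% of kept cells in CLL and 10.2 ± 6.60% in SHAM (mean ± SD, n = 3 each), with no overlap. Mural-like cells, the vessel-wrapping cells marked by Rgs5 and Myh11, were 0.361 ± 0.163% and 3.12 ± 2.32%. Fibroblast/tenocyte-like cells, the matrix makers, were 34.7 ± 13.3% in CLL and 13.03 ± 8.10% in SHAM, counting named clusters only, again without overlap. Macrophage/monocyte-like cells, the class the liposomes were aimed at, were 15.8 ± 8.15% and 20.97 ± 12.3%, and dendritic-like cells 5.50 ± 4.22% and 4.01 ± 3.09%. Myogenic-like cells, the muscle precursors, were 8.09 ± 3.26% and 6.08 ± 3.97%. Myofibre-like cells were 1.42 ± 0.514% and 1.66 ± 2.22%, and glial-like cells 0.999 ± 1.06% and 1.53 ± 0.909%. Adipocyte-like cells, led by Hp, Car3 and Adipoq, were 2.38 ± 3.34% in CLL and 0.0664 ± 0.0831% in SHAM, with CLL replicate 2 alone at 6.24%.

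No share passed. The two-sided exact permutation p was 0.10, the smallest 3 against 3 can give, for endothelial-like, fibroblast/tenocyte-like and adipocyte-like cells. It was 0.20 for mural-like cells and at least 0.50 for the rest, and the smallest value adjusted over 9 classes was 0.30. Cell numbers tested with edgeR, an alternative, passed for endothelial-like cells (log2 fold -2.88, adjusted p = 0.0447), mural-like cells (-3.11, 0.0447) and adipocyte-like cells (5.61, 0.00195). Per myogenic-like cell, endothelial-like cells numbered 0.223 ± 0.199 in CLL and 1.72 ± 0.340 in SHAM, and macrophage/monocyte-like cells 1.87 ± 0.350 and 3.77 ± 0.782. Fibroblast/tenocyte-like cells per myogenic-like cell were 4.33 ± 0.128 and 2.27 ± 0.471. Each of these 3 ratios parted the groups, with the smallest exact p of 0.10. Unnamed cells were 29.3 ± 23.4% in CLL and 39.4 ± 37.5% in SHAM, and shares moved with them. Fibroblast/tenocyte was the best-scoring list of several unnamed clusters. Among them, cluster 24 held 4416 cells of SHAM replicate 3 and cluster 12 held 4296 of CLL replicate 2. The fibroblast/tenocyte-like share and ratio, and their lack of overlap, therefore hold for named clusters only. Without SHAM replicate 1 the macrophage/monocyte-like difference turned to 0.0564 percentage points higher in CLL. Over all kept cells, named or not, macrophage/monocyte markers summed to 3482 CPM in CLL and 11040 CPM in SHAM. Of the 17 tested by edgeR, 14 fell and none rose. That sum mixes cell numbers with expression per cell.

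**Figure D1:**
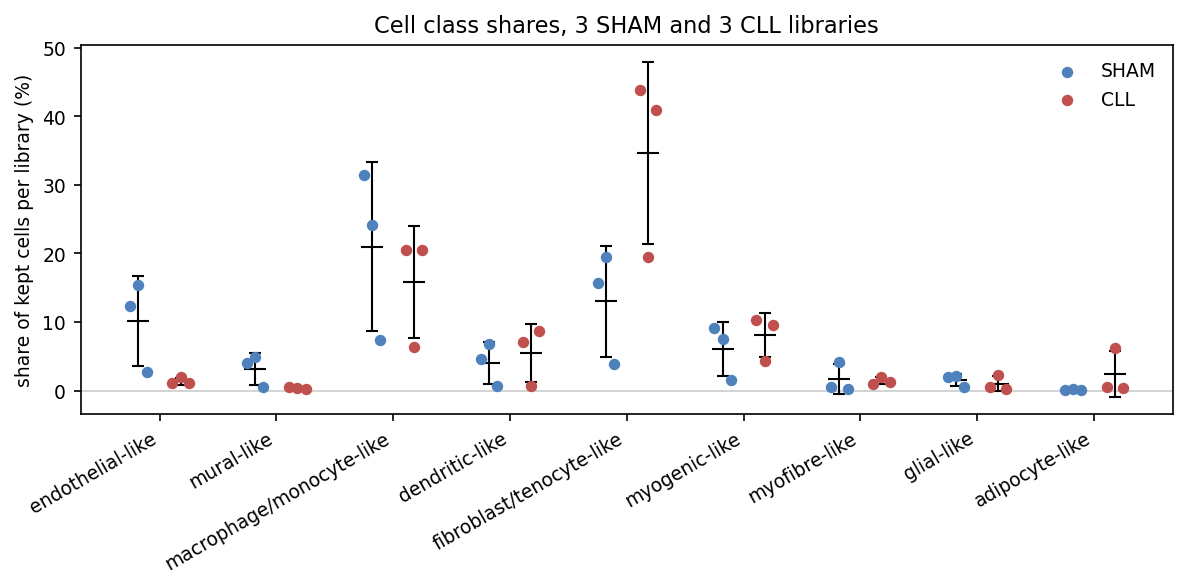
Share of kept cells in each class (%, vertical axis) for 3 SHAM and 3 CLL libraries; points are libraries and bars show mean ± SD. Endothelial-like shares of 1.05% to 1.97% in CLL lie below the SHAM shares of 2.76% to 15.4%.

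How endothelial cells responded to partial monocyte ablation was asked next, as the series title names their transition to mesenchymal cells. Endothelial-like cells numbered 39, 200 and 59 in CLL and 2387, 285 and 170 in SHAM. EdgeR found 7 genes higher and 22 lower in CLL of 9112 tested. Unadjusted, 714 had a p under 0.05, and DESeq2 called 58. Pgf, a growth factor of the VEGF family, rose from 22.6 ± 3.97 to 119 ± 42.5 CPM (log2 fold 2.39 ± 0.28 SE, adjusted p = 0.00179). The tip-cell gene Esm1 rose from 12.8 ± 4.75 to 86.95 ± 55.1 CPM (adjusted p = 0.0174), and the leukocyte adhesion molecule Icam1 from 68.7 ± 18.8 to 212 ± 55.6 CPM (adjusted p = 0.0239). The vasoconstrictor gene Edn1 rose from 37.4 ± 16.1 to 148 ± 57.6 CPM (adjusted p = 0.0311) and the matricellular gene Thbs1 from 74.97 ± 20.02 to 224 ± 51.1 CPM (adjusted p = 0.0239). Ifit1, an interferon-induced antiviral gene, fell from 68.8 ± 5.43 to 8.76 ± 3.11 CPM (log2 fold -3.07 ± 0.38 SE, adjusted p = 0.00197). The ubiquitin-like modifier Isg15 fell from 179.5 ± 50.7 to 37.3 ± 9.51 CPM (adjusted p = 0.00860).

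Of the 12 mural markers tested in endothelial-like cells, 6 fell, and their summed level was 612 CPM in CLL and 1921 CPM in SHAM. Vtn, a matrix glycoprotein gene, was 53.8 ± 4.99 CPM in SHAM and 0 in CLL, at least 14.8-fold lower (floor of 3 counts over the group). In SHAM it was 10.6 times higher in mural-like than in endothelial-like cells. Steap4, a metal reductase gene, fell from 59.4 ± 10.5 to 4.38 ± 3.98 CPM and was 7.68 times higher in mural-like cells of SHAM. The 5 lymphatic endothelial markers tested summed to 995 CPM in CLL and 153 CPM in SHAM, and none of them passed.

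Transition genes fixed for this class did not pass. Cdh5, the junctional cadherin, was 1020.2 ± 241 CPM in CLL and 1452 ± 113 CPM in SHAM (log2 fold -0.51 ± 0.25 SE, adjusted p = 0.674). The adhesion gene Pecam1 was 963 ± 109 and 884 ± 97.96 CPM (0.12 ± 0.23 SE). Among mesenchymal genes, the fibronectin gene Fn1 had a log2 fold of 0.70 ± 0.31 SE and the filament gene Vim 0.29 ± 0.28. The collagen genes Col1a1 and Col3a1 had 0.44 ± 0.34 and 0.10 ± 0.30, and the contractile genes Acta2 and Tagln -0.30 ± 0.49 and 0.15 ± 0.37. The transcription factor Snai1 had 0.33 ± 0.39 and the growth factor gene Tgfb1 -0.18 ± 0.27. Adjusted p (edgeR) was 0.6002 or more for all 10 fixed genes.

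Of 24 lists, 10 ranked higher and 3 lower in endothelial-like cells by camera, and none passed with an estimated correlation. The interferon response ranked lower in CLL (median log2 fold -1.09, camera adjusted p = 5.04e-31, adjusted p = 0.17 with an estimated correlation). Of its 27 genes 4 fell, namely Ifit1, Isg15, the receptor transporter gene Rtp4 and the GTPase gene Irgm1, and adjusted over the list alone 18 fell. Proliferation genes ranked lower (median -0.87, camera adjusted p = 5.64e-18, adjusted p = 0.15 with an estimated correlation). None of the 31 passed over all genes by the unblocked edgeR fit, where 9 fell adjusted over the list alone, while 4 fell over all genes in the blocked fit. Leukocyte adhesion and acute inflammation ranked higher (median 0.50, camera adjusted p = 3.26e-04, adjusted p = 0.35 with an estimated correlation). Icam1 rose, the chemokine gene Cxcl10 fell from 156 ± 44.8 to 45.8 ± 18.8 CPM, and 22 did not pass, with 7 risen and 2 fallen adjusted over the list alone. Angiogenic sprouting ranked higher (median 0.15, camera adjusted p = 0.00159, adjusted p = 0.24 with an estimated correlation). Pgf and Esm1 rose, none of the 24 fell, and 3 rose adjusted over the list alone.

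TGF-beta and BMP signalling ranked higher in endothelial-like cells (median 0.18, camera adjusted p = 1.03e-04, adjusted p = 0.25 with an estimated correlation), with 2 of 30 risen, among them the latent TGF-beta binding gene Ltbp2, and 2 adjusted over the list alone. Glycolysis and hypoxia ranked higher (median 0.36, camera adjusted p = 2.24e-06, adjusted p = 0.21 with an estimated correlation). None of its 26 genes passed over all genes by edgeR, and 1 rose adjusted over the list alone, the lactate exporter gene Slc16a3. The mesenchymal genes of endothelial-to-mesenchymal transition ranked higher (median 0.29, camera adjusted p = 9.74e-04, adjusted p = 0.52 with an estimated correlation). Of 27 genes 1 rose, the mural marker Pdgfrb fell and 25 did not pass, with 2 risen and 1 fallen adjusted over the list alone. Markers of other classes carried by these cells were higher as well, 5670.3 CPM in CLL and 4371 CPM in SHAM for fibroblast markers and 355 and 144 CPM for tenocyte markers (median log2 fold 1.32), with none past edgeR. Endothelial identity did not pass (median -0.12, camera adjusted p = 0.279, adjusted p = 0.76 with an estimated correlation), and none of its 20 genes changed by the unblocked edgeR fit, over all genes or over the list alone, while 1 fell in the blocked fit, the transcription factor gene Sox18.

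These endothelial-like calls rest on few CLL cells. They numbered 6 without CLL replicate 3, 16 without CLL replicate 1 and 13 without SHAM replicate 3. Pgf, Vtn and Ifit1 passed in all 6 such fits, while Esm1, Edn1, Icam1 and Thbs1 did not in those 3. Isg15 lost its call without CLL replicate 1 or 3, and Steap4 without CLL replicate 3. Of the 20 named genes that passed, 16 no longer did without CLL replicate 3. The blocked fit, in which replicate numbers were treated as pairs on the basis of these same counts, called 131 genes, 56 higher and 75 lower. It added the chemokine gene Ccl2, S100a4 and Nfkbia to those higher, and Sox18 and the proliferation genes Tk1, Ccnb2, Ube2c and Stmn1 to those lower. By list it called 9 interferon genes lower, 5 leukocyte adhesion genes higher and 1 lower, and 3 mesenchymal genes higher and 1 lower. Leaving out endothelial-like cells with UMIs of at least 2 mural markers was an alternative chosen after the data were seen. It left 0 of 6096 genes called by edgeR, 446 at an unadjusted p under 0.05 and 16 by DESeq2. There Ifit1 had a log2 fold of -2.84 ± 0.53 SE (adjusted p = 0.0898).

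Whether more endothelial cells carried mesenchymal transcripts after partial monocyte ablation was asked next. With every cell drawn down to 1000 UMIs, 81.7 ± 6.21% of endothelial-like cells in CLL and 78.3 ± 11.99% in SHAM had UMIs of at least 2 of 8 mesenchymal genes. The difference was 3.47 percentage points (two-sided exact permutation p = 0.80). It was 10.4 without SHAM replicate 1 and -0.0352 without SHAM replicate 3. This used 224 CLL and 2457 SHAM cells, at median depths of 2257 and 2834 UMIs, and left out 74 and 385 shallower ones. Before drawing down, the shares were 100% and 98.6 ± 1.90%. Such UMIs were also common elsewhere. They were found in 57.5 ± 5.63% and 56.9 ± 29.9% of macrophage/monocyte-like cells (median 7145 and 3084 UMIs) and 66.5 ± 1.81% and 74.1 ± 23.1% of dendritic-like cells (median 5453 and 2337 UMIs). In cluster 20, the T/NK and neutrophil cells, they were found in 80.3 ± 8.21% and 78.5 ± 18.6% (median 4041 and 1959 UMIs), a share above the endothelial-like one in SHAM. The endothelial-like share was above the macrophage/monocyte-like one in all 6 libraries. Where the UMIs came from was not tested, and no increase of the endothelial-like share in CLL was shown at this depth. The share covers only cells of the cluster named endothelial-like. Cluster 25, whose best-scoring list was endothelial, was left unnamed because it held markers of a second class. Cluster 25 had 0 cells in each CLL library and 172, 4 and 7 in SHAM replicates 1 to 3. Cells with markers of both kinds may thus be missing from this share.

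**Figure D2:**
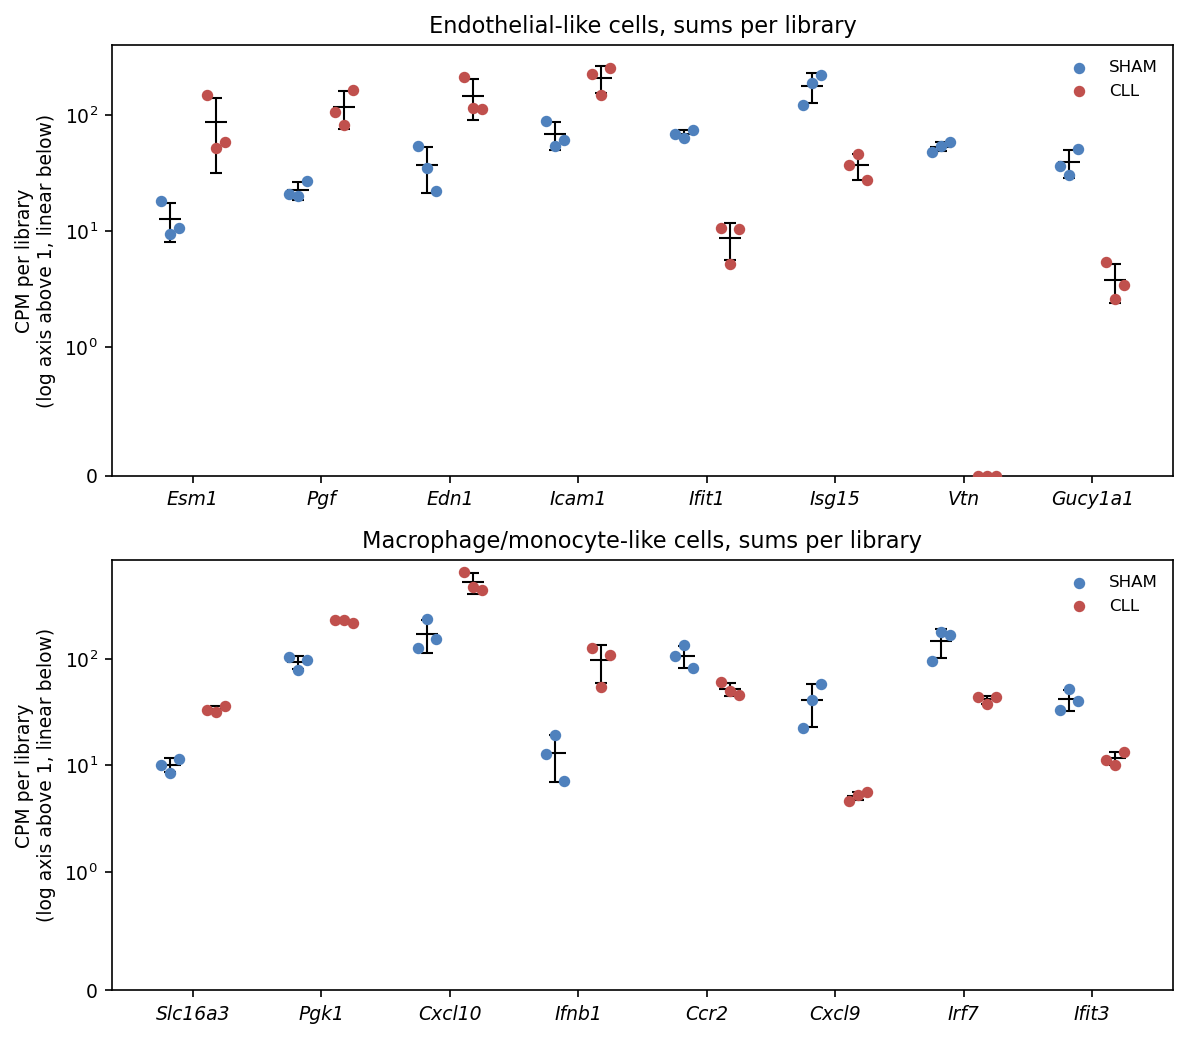
CPM per library (vertical axes, logarithmic above 1 and linear below) of named genes in endothelial-like (top) and macrophage/monocyte-like cells (bottom); points are libraries and bars show mean ± SD of 3. In endothelial-like cells Esm1 and Pgf lie higher and Ifit1 and Vtn lower in all 3 CLL libraries, and in macrophage/monocyte-like cells Slc16a3 and Pgk1 lie higher and Cxcl9 and Irf7 lower in all 3.

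How the remaining macrophages and monocytes differed was the question in the targeted class. EdgeR found 189 genes higher and 284 lower in CLL of 11650 tested. Slc16a3, the lactate exporter, rose from 10.1 ± 1.52 to 33.6 ± 2.34 CPM (log2 fold 1.72 ± 0.15 SE, adjusted p = 0.00285). The glycolytic kinase gene Pgk1 rose from 93.9 ± 13.4 to 227 ± 6.99 CPM (1.27 ± 0.14 SE, adjusted p = 0.00357). Ifnb1, which encodes interferon beta, rose from 13.04 ± 6.11 to 96.6 ± 37.7 CPM (2.94 ± 0.37 SE, adjusted p = 0.00552), while 18 of 28 interferon response genes fell. Cxcl9, a T-cell-attracting chemokine gene, fell from 40.7 ± 17.8 to 5.20 ± 0.491 CPM (-2.95 ± 0.34 SE, adjusted p = 0.00488). The interferon regulator gene Irf7 fell from 147 ± 45.2 to 41.6 ± 3.66 CPM (adjusted p = 0.00552). Cxcl10, a chemokine gene related to Cxcl9, rose from 172 ± 57.4 to 523 ± 115 CPM (adjusted p = 0.0123). Ccr2, the receptor that brings monocytes out of the blood, fell from 107 ± 25.9 to 51.9 ± 7.25 CPM (adjusted p = 0.0225). Of the other fixed genes, the monocyte gene Ly6c2 (log2 fold -1.02 ± 0.60 SE), the mannose receptor gene Mrc1 (0.22 ± 0.29), Gpnmb (0.07 ± 0.36), Adgre1 (0.12 ± 0.13) and the growth factor receptor gene Csf1r (-0.33 ± 0.17) did not pass.

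By list, glycolysis and hypoxia ranked higher in macrophage/monocyte-like cells (median log2 fold 0.75, camera adjusted p = 6.15e-22) and passed at adjusted p = 0.0186 with an estimated correlation. Of its 28 genes 13 rose, among them Slc16a3, Pgk1, the isomerase gene Tpi1 and the pyruvate kinase gene Pkm, and none fell; adjusted over the list alone 20 rose and 1 fell. The interferon response ranked lower (median -1.11, camera adjusted p = 1.37e-32, adjusted p = 0.20 with an estimated correlation). Those that fell included Ifit3, Irgm1 and the nucleic acid sensor gene Zbp1, and adjusted over the list alone 24 fell and 1 rose. MHC class II presentation ranked lower (median -1.53, camera adjusted p = 5.69e-16, adjusted p = 0.20 with an estimated correlation). Of 8 genes 7 fell, over all genes and over the list alone, including the master regulator Ciita, from 25.4 ± 4.07 to 6.15 ± 0.505 CPM, and H2-Ab1, from 2614 ± 967 to 818 ± 256 CPM. Proliferation ranked higher (median 0.93, camera adjusted p = 1.78e-25, adjusted p = 0.26 with an estimated correlation). Of 31 genes 11 rose, including the cycling marker Mki67, from 38.97 ± 10.9 to 90.6 ± 14.6 CPM, and the replication licensing genes Mcm3 and Mcm5, and 27 rose adjusted over the list alone. MHC class I presentation ranked lower (median -0.67, adjusted p = 0.26 with an estimated correlation), with 6 of 15 fallen and 13 adjusted over the list alone. Leukocyte adhesion and acute inflammation ranked higher (median 0.27, adjusted p = 0.53 with an estimated correlation), with Cxcl10, Cxcl1, Tnf and Ccl2 risen of 23, the same 4 over the list alone. Infiltrating monocyte genes (median -0.26, 2 risen and 2 fallen of 17) did not pass camera, nor did resident-type (0.05, 2 fallen of 18) or repair-type macrophage genes (0.07, 2 fallen of 25).

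Within the class, cluster shares are given as means of each group's libraries. The cluster led by F13a1, Ccl8 and Mrc1 made up 50.04% in CLL and 15.2% in SHAM, and that led by Gpnmb and Mmp12 22.4% and 13.3%. The cluster led by H2-Aa and Cd74 was 20.4% and 41.05%, and that led by Gpnmb and C1qb 7.08% and 30.4%. In the same order, the glycolysis median in each cluster alone was 1.03, 0.59, 0.64 and 0.77. Only the glycolysis and interferon lists were tested within clusters. The fall of MHC class II genes, which lead the H2-Aa and Cd74 cluster, is thus not set apart from the cluster mix. The shares overlapped between the groups for each of these clusters but the F13a1 one. In SHAM replicates 1 to 3 the Gpnmb and C1qb cluster held 84 of 6074, 138 of 447 and 267 of 452 class cells. In CLL replicates 1 to 3 it held 76 of 728, 10 of 650 and 107 of 1156. Its median mitochondrial share was 0.214%, and SHAM replicate 3 had the lowest library median, 0.127%. Endothelial markers were carried at low level, 15.5 CPM in CLL and 48.7 CPM in SHAM summed over 9 genes of which 2 fell. The count of 473 changed genes was 21 without CLL replicate 1, 48 without CLL replicate 3, 152 without SHAM replicate 3 and 255 without CLL replicate 2. It was 1 with each library clustered on its own and 290 scaled by library totals, 24.5% of them higher in CLL against 39.96% with TMM. In all 6 fits that left out a library Slc16a3, Pgk1, Ifnb1, Cxcl9, Ifit3, Irgm1, Zbp1 and Ciita passed. Ccr2 and H2-Ab1 lost their call when any CLL library was left out, Tpi1, Irf7 and Mcm3 without CLL replicate 1, and Pkm, Cxcl10, Mki67 and Mcm5 without CLL replicate 1 or 3. Of the 39 named genes that passed, 29 no longer did without CLL replicate 1 and 25 without CLL replicate 3.

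**Figure D3:**
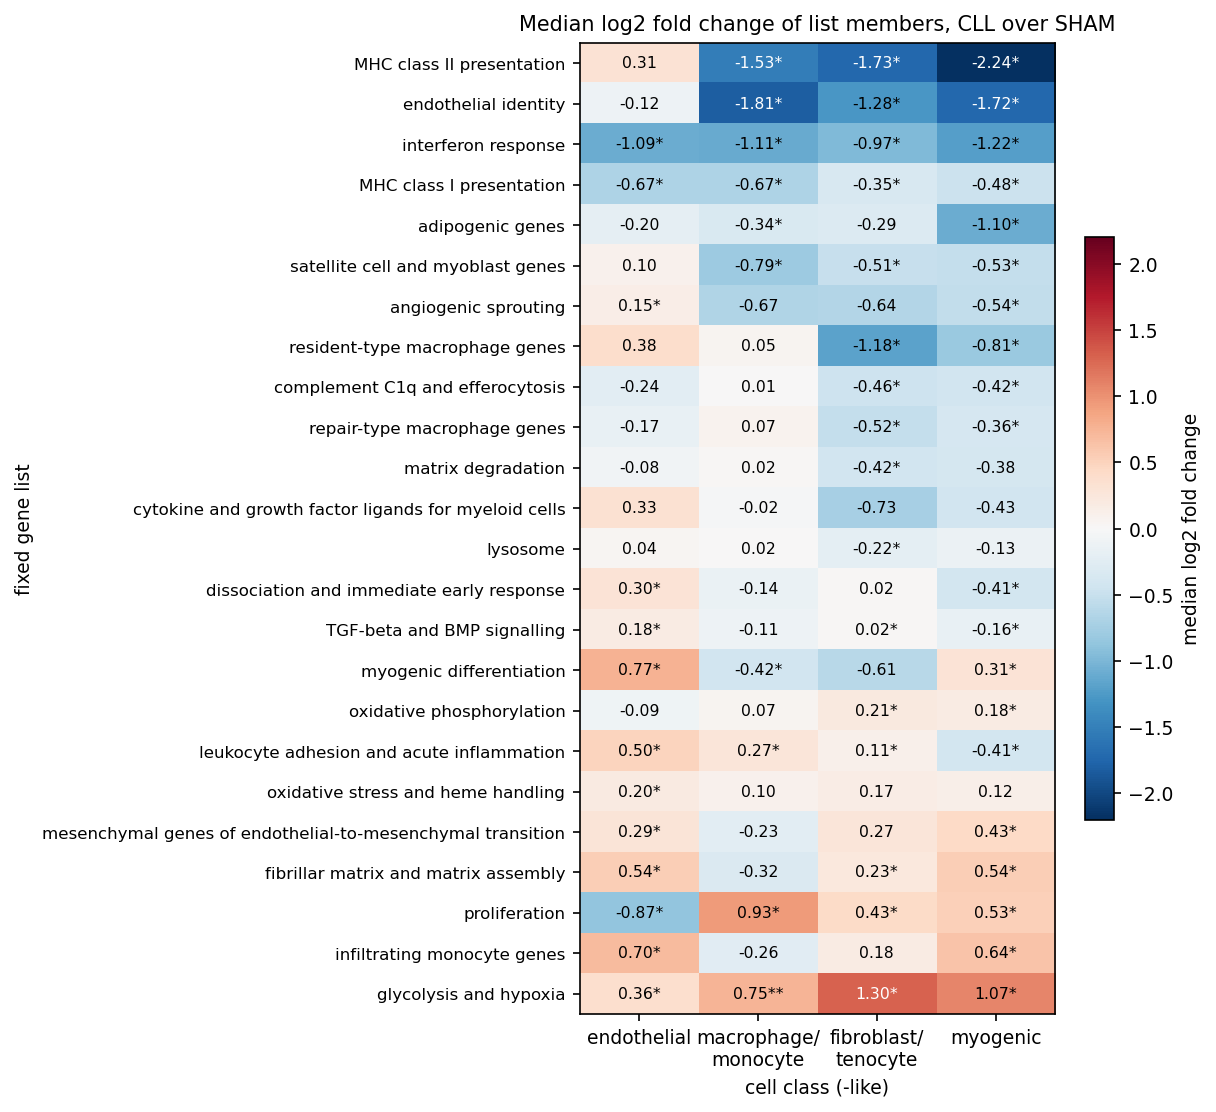
Median log2 fold change, CLL over SHAM, of the members of 24 gene lists (vertical axis) in 4 cell classes (horizontal axis); 1 star marks lists past camera at the preset correlation and a pair of stars those also past it with an estimated correlation. The interferon response was at -0.97 to -1.22 and glycolysis and hypoxia at 0.36 to 1.304 in the 4 classes.

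In fibroblast/tenocyte-like cells, where the question was how matrix-producing cells fared after partial monocyte ablation, edgeR found 1672 genes higher and 1848 lower of 14329. Ccl2, a chemokine gene that recruits monocytes, rose from 192 ± 8.25 to 933 ± 150.2 CPM (log2 fold 2.28 ± 0.15 SE, adjusted p = 1.16e-04). Csf1, the macrophage growth factor gene, rose from 56.3 ± 3.44 to 94.4 ± 10.1 CPM (0.74 ± 0.12 SE, adjusted p = 0.00245). Slc16a3 rose from 10.96 ± 4.31 to 84.9 ± 19.7 CPM (2.91 ± 0.26 SE, adjusted p = 1.99e-04) and the sterol synthesis enzyme gene Fdps from 17.96 ± 3.06 to 86.2 ± 20.5 CPM. Igf2, an imprinted growth factor gene, fell from 381 ± 83.3 to 32.9 ± 14.1 CPM (-3.53 ± 0.30 SE, adjusted p = 1.66e-04), and the imprinted Notch-ligand-like gene Dlk1 from 326 ± 135 to 27.1 ± 3.65 CPM. Pdgfra, the receptor that marks fibro-adipogenic progenitors, fell from 211 ± 34.2 to 85.1 ± 11.7 CPM (-1.31 ± 0.15 SE, adjusted p = 6.26e-04). The matrix genes Col1a1 (-0.12 ± 0.14) and Postn (0.31 ± 0.13) did not pass.

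By list, glycolysis and hypoxia ranked higher in fibroblast/tenocyte-like cells (median 1.304, camera adjusted p = 1.48e-32, adjusted p = 0.22 with an estimated correlation). Of 28 genes 25 rose, over all genes and over the list alone, including Tpi1, the phosphofructokinase gene Pfkl and Pkm, and none fell. The interferon response ranked lower (median -0.97, camera adjusted p = 1.51e-19, adjusted p = 0.22 with an estimated correlation). Of 28 genes 23 fell, including the GTPase gene Iigp1, from 72.6 ± 20.8 to 21.00 ± 2.94 CPM, and Oasl2, and 25 fell adjusted over the list alone. Fibrillar matrix and matrix assembly was mixed (median 0.23, camera adjusted p = 0.00870, adjusted p = 0.22 with an estimated correlation). Of 28 genes 11 rose, including the collagen crosslinker Lox, from 441 ± 57.8 to 1153 ± 83.7 CPM, and Cthrc1, while 5 fell, including the proteoglycan gene Lum, from 1063 ± 204 to 444 ± 54.3 CPM. The counts were the same adjusted over the list alone. Leukocyte adhesion and acute inflammation ranked higher (median 0.11, adjusted p = 0.22 with an estimated correlation), with 11 of 27 risen, including Ccl2 and Ccl7, and 4 fallen, the same counts as over the list alone. Satellite cell and myoblast genes ranked lower (median -0.51, adjusted p = 0.22 with an estimated correlation), with 7 of 15 fallen, including the receptor tyrosine kinase inhibitor Spry1, and 9 fallen and 1 risen adjusted over the list alone. Myogenic markers carried by these cells were lower too, at 36.6 CPM in CLL and 63.6 CPM in SHAM, with 4 of 10 fallen.

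The fibroblast/tenocyte-like class differed in make-up. As means of each group's libraries, the cluster led by Ddah1, Cthrc1 and Lox was 61.6% of it in CLL and 23.2% in SHAM. That led by Ptn, Clec3b and Lum was 17.9% and 54.3%, and that led by Pi16 and Dlk1 2.58% and 14.9%. The last of these overlapped between the groups. In SHAM replicates 1 to 3 it held 18 of 3031, 51 of 360 and 73 of 243 class cells. In CLL replicates 1 to 3 it held 49 of 1554, 64 of 1977 and 31 of 2303. Its median mitochondrial share was 0.295%, and SHAM replicate 3 had the lowest library median, 0.127%. Macrophage/monocyte markers were carried at 215 CPM in CLL and 484 CPM in SHAM, with 11 of 13 fallen. Mural markers were at 2737 and 905 CPM, with 3 of 12 risen and 7 fallen. Endothelial markers were at 22.4 and 61.3 CPM, with 7 of 11 fallen. Within clusters led by fibroblast markers, a split chosen after the data were seen, 3543 genes passed. That split keeps all 3 of these clusters, so it does not set the shift in make-up aside. Slc16a3, Ccl2, Csf1, Igf2, Dlk1 and Pdgfra passed in all 6 fits that left out a library. The count was 1969 without CLL replicate 1 and 1877 without CLL replicate 3. Scaled by library totals, 31.01% of the called genes were higher in CLL against 47.5% with TMM.

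In myogenic-like cells the comparison asked how muscle stem and precursor cells responded. EdgeR found 802 genes higher and 800 lower of 11216. Timp1, a metalloprotease inhibitor gene, rose from 114 ± 24.05 to 493 ± 56.2 CPM (log2 fold 2.10 ± 0.17 SE, adjusted p = 4.38e-05). The secreted phosphoprotein gene Spp1 rose from 309.9 ± 117 to 1039 ± 101 CPM (1.74 ± 0.23 SE, adjusted p = 6.72e-04). Pax7, the satellite cell transcription factor, fell from 170.1 ± 13.99 to 94.6 ± 14.3 CPM (-0.86 ± 0.14 SE, adjusted p = 0.00289). Col15a1, a basement membrane collagen gene, fell from 57.4 ± 7.85 to 4.39 ± 0.656 CPM (-3.68 ± 0.19 SE, adjusted p = 1.96e-06) and was 12.5 times higher in endothelial-like cells of SHAM. Chodl, a membrane lectin gene, fell from 202 ± 40.1 to 16.9 ± 6.81 CPM. The myoblast gene Myod1 (-0.07 ± 0.17) and the later differentiation genes Myog (-0.17 ± 0.25), Mymk (0.07 ± 0.20) and Myh3 (0.91 ± 0.36) did not pass.

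By list, the interferon response ranked lower in myogenic-like cells (median -1.22, camera adjusted p = 7.66e-18, adjusted p = 0.17 with an estimated correlation). Of 26 genes 16 fell, including Iigp1, from 83.2 ± 20.3 to 9.24 ± 3.07 CPM, Irgm1 and the regulator gene Irf1, and 17 adjusted over the list alone. Satellite cell and myoblast genes ranked lower (median -0.53, camera adjusted p = 6.36e-07, adjusted p = 0.0579 with an estimated correlation). Of 18 genes 10 fell, including Pax7 and the quiescence receptor gene Calcr, from 12.1 ± 1.09 to 0.803 ± 0.862 CPM, and 1 rose, with 13 fallen and 1 risen adjusted over the list alone. Adipogenic genes ranked lower (median -1.10, camera adjusted p = 1.41e-09, adjusted p = 0.0579 with an estimated correlation). Of 10 genes 7 fell over all genes and over the list alone, including the transcription factor gene Cebpd, from 215 ± 34.5 to 56.2 ± 12.7 CPM, and Apoe, which was 44.6 times higher in macrophage/monocyte-like cells of SHAM. Glycolysis and hypoxia ranked higher (median 1.07, camera adjusted p = 3.31e-14, adjusted p = 0.29 with an estimated correlation). Of 27 genes 15 rose, including the lactate dehydrogenase gene Ldha, from 165 ± 12.2 to 449 ± 133 CPM, and 2 fell, with 21 and 2 adjusted over the list alone. Proliferation ranked higher (median 0.53, adjusted p = 0.36 with an estimated correlation), with 8 of 31 risen, including the cyclin gene Ccnb2, and 13 adjusted over the list alone.

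Macrophage/monocyte markers were carried by myogenic-like cells at 127 CPM in CLL and 319.99 CPM in SHAM, with 7 of 12 fallen. Mural markers, contractile genes among them, were at 3394 and 1321 CPM, with 3 of 9 risen and 1 fallen. Endothelial markers, like Col15a1 genes of a higher level in endothelial-like cells, were at 6.75 and 31.5 CPM, with 3 of 3 fallen, and fibroblast markers at 5678 and 4352 CPM, with 1 of 13 risen and 3 fallen. Without cells that carried UMIs of at least 3 macrophage markers 1046 genes passed. The count was 790 without CLL replicate 1, 541 without CLL replicate 3 and 445 with each library clustered on its own. Timp1, Spp1, Pax7, Col15a1, Chodl, Iigp1 and Calcr passed in all 6 fits that left out a library. Scaled by library totals, 24.9% of the called genes were higher in CLL against 50.1% with TMM.

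Of the remaining classes, only dendritic-like cells had at least 20 cells in every library. There edgeR called 17 genes higher and 37 lower of 7752, with 1001 at an unadjusted p under 0.05, and DESeq2 called 18 and 36. The dendritic-like count of 54 was 1 without CLL replicate 3, 8 without CLL replicate 1, 27 without CLL replicate 2 and 232 without SHAM replicate 1.

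Summing all kept cells, which needs no cell classes but mixes make-up with expression, asked what changed in the tissue. EdgeR found 2935 genes higher and 3170 lower of 16687. Endothelial identity genes fell together, 20 of 20 over all genes and over the list alone (median -3.75, camera adjusted p = 4.72e-33, adjusted p = 0.12 with an estimated correlation). The sialomucin gene Emcn fell from 47.7 ± 9.66 to 2.01 ± 0.978 CPM (-4.57 ± 0.36 SE, adjusted p = 1.43e-04) and the VEGF receptor gene Kdr from 62.4 ± 14.7 to 3.75 ± 1.99 CPM (-4.06 ± 0.37 SE, adjusted p = 2.24e-04). Fibrillar matrix genes ranked higher (median 0.94, adjusted p = 0.12 with an estimated correlation), with 23 of 28 risen and none fallen, and 24 and 1 adjusted over the list alone. Lox rose from 191 ± 14.5 to 839 ± 124 CPM (2.13 ± 0.14 SE, adjusted p = 9.88e-05). Glycolysis and hypoxia ranked higher (median 1.33, adjusted p = 0.17 with an estimated correlation), with 22 of 28 risen and 1 fallen, and 24 and 1 over the list alone. Interferon response genes ranked lower (median -1.43, adjusted p = 0.12 with an estimated correlation), with 27 of 28 fallen and 28 over the list alone. The largest rises were adipocyte genes. The haptoglobin gene Hp (6.33 ± 0.95 SE, adjusted p = 0.00178) rose from 7.89 ± 2.31 to 637 ± 749 CPM, with 1498 CPM in CLL replicate 2 and 134 and 279 CPM in CLL replicates 1 and 3.

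Whether endothelial-like and fibroblast/tenocyte-like cells changed differently was tested directly with a class-by-treatment interaction. Of 13994 genes, edgeR called 256, 111 with a more positive and 145 with a more negative effect in endothelial-like cells, and 1960 had an unadjusted p under 0.05. Icam1 responded more positively in endothelial-like cells (difference of log2 folds 1.70 ± 0.26 SE, adjusted p = 0.00414). So did Igf2, which fell in fibroblast/tenocyte-like cells and did not pass in endothelial-like cells (2.94 ± 0.33 SE, adjusted p = 2.42e-04). Acta2, itself a mural marker (-2.05 ± 0.40 SE, adjusted p = 0.0152), and Ldha (-1.50 ± 0.24 SE, adjusted p = 0.00471) had a more negative effect in endothelial-like cells. Both rose in fibroblast/tenocyte-like cells and did not pass in endothelial-like cells, where the fold of Acta2 was -0.30 and turned to 0.80 without cells carrying mural markers. These 4 genes were singled out after their values were seen. Of the called genes, 83 were under 10% of the level of their highest class in at least 1 of the classes compared (SHAM), so carried RNA is not set apart from a response there. The interaction count was 9 without CLL replicate 1, 99 without CLL replicate 2, 112 without CLL replicate 3 and 456 without SHAM replicate 2.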

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

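The tests of free mural RNA, of dilution, of how well vessel cells were freed, of free fibroblast RNA, of the macrophage cluster mix and of cells of different depth were chosen only after the results they bear on were seen, as was the fit without cells carrying mural markers. The tests of attached mural cells, of cells lost in filtering or naming and of other splits were set before their own results were seen.

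The change with CLL differed between endothelial-like and fibroblast/tenocyte-like sums in 256 of 13994 genes by the class-by-treatment interaction (edgeR, library as a block). It drew attention as a difference between groups of cells under the same treatment, but part of the count is of genes that another class holds at a far higher level, so carried RNA is not set apart from a response. In SHAM, 83 of these genes were, in at least 1 of the classes compared, under 10% of their level in the class that held them highest, among them the endothelial gene Cdh5, which fell in fibroblast/tenocyte-like cells and did not pass in endothelial-like cells. Endothelial markers carried by fibroblast/tenocyte-like cells fell from 61.3 to 22.4 CPM (7 of 11 fallen). Among the called genes, Icam1, the leukocyte adhesion molecule, went up in endothelial-like cells, and Igf2, a growth factor gene, went down in fibroblast/tenocyte-like cells. Without SHAM replicate 2 the count was 456 and without CLL replicate 1 it was 9, so the number of such genes depended strongly on which libraries were in the fit. How much of the count is a difference in response was not tested.

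The Tomato reporter, which none of the planned comparisons used, stood out in endothelial-like cells. It was at 1871 ± 633 CPM in SHAM and 1513 ± 228 CPM in CLL (two-sided exact permutation p = 0.60, n = 3 each). Macrophage/monocyte-like cells, taken as background, held 75.2 ± 21.9 and 65.7 ± 7.11 CPM. Drawn down to 1000 UMIs, 65.2 ± 20.6% of endothelial-like cells in SHAM and 65.8 ± 9.59% in CLL had a Tomato UMI, against 7.32 ± 2.65% and 6.50 ± 0.332% of macrophage/monocyte-like cells (median depths 3084 and 7145 UMIs). These values used 2457 and 224 endothelial-like cells, with 385 and 74 left out, at median depths of 2834 and 2257 UMIs. Before drawing down the shares were 78.2 ± 16.2% and 73.4 ± 3.104%. The labels do not say when the reporter was switched on.

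Mural genes were lower in endothelial-like cells of CLL libraries, and 11 of the 29 called genes were mural markers or mural-specific. Leaving out cells with UMIs of at least 2 mural markers took away 63.6% of the SHAM level of 27 mural-specific genes (864 to 315 CPM) and left the CLL level at 245 CPM (239 before). Over the 7 of them still tested the median log2 fold was -1.08 before and -0.23 after. Mural RNA brought by attached cells cannot be told apart from mural genes that these cells express themselves, because leaving out cells by their mural UMIs lowers that RNA in either case. For free mural RNA, macrophage/monocyte-like cells of SHAM held those genes at 9.57% of the endothelial-like level. That value does not decide, because the genes were chosen to be at least 10 times higher in mural-like than in macrophage/monocyte-like cells of SHAM. Mural markers, not chosen that way, summed in SHAM to 146 CPM in macrophage/monocyte-like cells (9 tested) and 1921 CPM in endothelial-like cells (12 tested). This goes against free mural RNA as the only source. With cells carrying UMIs of at least 2 mural markers left out, edgeR called 0 of 6096 genes, with 446 at an unadjusted p under 0.05 and 16 by DESeq2. Of the 7 genes called higher, 6 were still tested, with a median fold of 2.14 (median SE 0.29) before and 1.82 (SE 0.44) after. Of the 22 called lower, 10 were, with -2.04 (SE 0.34) before and -2.07 (SE 0.44) after. The spread of both sets thus widened, and the 12 lower genes no longer tested were all higher in mural-like than in endothelial-like cells of SHAM. A true loss of mural contact in CLL muscle stays open and untested.

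Endothelial-like cells were a smaller share of kept cells in every CLL library than in any SHAM library. Dilution by other classes as the whole cause is argued against, since the highest CLL ratio to myogenic-like cells was 0.333 of the lowest SHAM ratio. Myogenic-like cells were themselves 8.09% of kept cells in CLL and 6.08% in SHAM, so a part of that ratio may be dilution. To glial-like cells, of which a CLL library held as few as 17, the highest CLL ratio was 0.612 of the lowest SHAM ratio. This was also without overlap but not under 50%, so dilution as a part of the cause stays open. Loss in filtering or naming is argued against too: over all barcodes the highest CLL level of summed endothelial markers was 0.140 of the lowest SHAM level (57.3 ± 27.4 against 838 ± 211 CPM, exact p = 0.10). Vessel cells freed less well from CLL muscle, with the mural-like share also lower in CLL (-2.76 percentage points, overlapping groups, exact p = 0.20), cannot be told apart from fewer vessel cells in the tissue, because no tissue measure of vessels was used here. Over all barcodes mural markers summed to 2173 ± 280.1 CPM in CLL and 1284 ± 372 CPM in SHAM (exact p = 0.10), the other direction. In all kept cells summed, 8 of these 12 markers fell while Acta2, Tagln and Ndufa4l2 rose, and fibroblast/tenocyte-like cells also carried more mural-marker RNA in CLL, so that sum does not measure mural cells alone. A biological loss of vessels under the treatment therefore remains a possible explanation, not tested here.

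Glycolysis genes were higher and interferon response genes lower in macrophage/monocyte-like, fibroblast/tenocyte-like and myogenic-like cells of CLL. A different mix of macrophage clusters is argued against: within each of 4 clusters alone both list medians were at least 0.613 of the class value. Free RNA from fibroblast-like cells as the whole cause is argued against too. At the share of it that fibroblast markers allow, it would give 9.79% of the change in summed glycolysis CPM in macrophage/monocyte-like and 21.9% in myogenic-like cells, at most 27.7% with a library left out, and less of the interferon change. In macrophage/monocyte-like cells those markers summed to 2510.4 CPM in CLL and 3154 CPM in SHAM with none risen, while 17 other fibroblast-specific genes had a median log2 fold of 0.31 (quartiles -0.57 and 0.71), under the glycolysis list's 0.75. Free RNA from other classes and the mix of clusters in the other classes were not tested. Depth per cell was tested among cells of 2000 to 6000 UMIs, drawn down to 2000, against the class value of the same genes. The glycolysis median was 0.728 of that value in macrophage/monocyte-like and 1.05 in fibroblast/tenocyte-like cells, and at least 0.601 with a library left out, so cells of different depth are argued against as the whole cause of the glycolysis change in these classes. The interferon median was 0.445 and 0.608 of that value (-0.38 against -0.85 and -0.41 against -0.68), and 0.294 to 0.788 and 0.468 to 1.05 with a library left out. For interferon genes depth therefore cannot be told apart from a change with CLL. Only 15 and 4 of the 28 were still tested, and a library held as few as 20 such cells. Myogenic-like cells had too few of them for this test. An effect of the treatment itself, or of days and runs that the labels do not give, may underlie both lists and was not tested.

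Splits of the 6 libraries into 3 and 3 were too few, 10 with the real one, for a share under 0.05. The real split was the 1 with the highest count throughout. Real and highest other counts of called genes were 29 and 0 in endothelial-like, 473 and 0 in macrophage/monocyte-like, 3520 and 0 in fibroblast/tenocyte-like and 1602 and 0 in myogenic-like cells. They were 54 and 3 in dendritic-like cells, 6105 and 0 in all cells summed and 256 and 3 for the interaction. For lists past camera at the preset correlation, over 4 classes, the real split gave 59 and each of the other splits 32 to 45, so passing that test alone was common in all of them. In endothelial-like cells, where replicate numbers were treated as pairs, the 3 other splits that part every same-number pair also gave 0.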

How the results depend on the processing

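The settings without cells under 0.5% mitochondrial UMIs, without cells carrying macrophage or mural markers, by leading cluster marker, in named clusters only, with another seed, without SHAM replicate 1 and CLL replicate 2 together, and all for dendritic-like cells, were chosen after seeing the data, so these tests are exploratory. Among values that answer a comparison, 321 stayed on their side under an alternative, 55 moved, 11 reversed and 3 came past the threshold. Class shares and the share with mesenchymal transcripts could not go below p = 0.10 by the exact permutation test. Under that test they could only stay or reverse, so their part of the 321 is no evidence of stability. Among single genes and lists, 4528 stayed, 429 no longer passed, 51 came to pass and 52 reversed. Where no construction is named, the cause was not tested.

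Endothelial-like calls (29) numbered 17 with at least 500 genes and 1000 UMIs, 7 with no doublets removed, 44 at resolution 0.5, 12 at resolution 2, 58 with DESeq2, 199 with no filter, 12 with limma-voom and 14 on thinned sums. They numbered 59 with both libraries left out, 18 without cells under 0.5% mitochondrial UMIs, 18 without cells with 3 macrophage markers and 0 by edgeR without cells with 2 mural markers (446 unadjusted, 16 by DESeq2). With each library clustered on its own edgeR called 0, from 2 libraries a group, since the class was named in only 4; no other tool was run on it. Leaving out each library gave 6 to 35. The 13 lists past camera were 0 with estimated correlation, 1 by fry and 10 to 16 without each library. They were 9 without cells with 2 mural markers, where TGF-beta and BMP signalling (adjusted p = 0.0932), angiogenic sprouting (0.44) and leukocyte adhesion (0.17) of the 7 discussed no longer passed, and 14 with each library clustered on its own, where the first and last of these were lost (0.0529 and 0.38) and angiogenic sprouting turned.

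Macrophage/monocyte-like calls (473) numbered 1 with each library clustered on its own, 290 with library totals, 1352 with no filter, 1068 with limma-voom and 21 to 611 without each library. Lists (10) were 1 with estimated correlation, 1 by fry and 9 to 13 without each library. Fibroblast/tenocyte-like calls (3520) numbered 0 by edgeR in the tenocyte-led cluster, where 2 libraries a group held 20 cells and no other tool was run, and 1877 to 3347 without each library. Lists (16) were 0 with estimated correlation, 9 by fry, 5 in the tenocyte-led cluster and 14 to 18. Myogenic-like calls (1602) numbered 445 with each library clustered on its own (the class was not named in SHAM replicate 3), 1046 without cells with 3 macrophage markers and 541 to 1561. Lists (20) were 0 with estimated correlation, 5 by fry and 15 to 19. All cells summed gave 4510 to 5975 (main 6105), with lists (14) 0 with estimated correlation and 13 to 15. Dendritic-like calls (54) numbered 253 with no filter and 1 to 232, the interaction (256) 728 and 9 to 456. Another seed gave 29, 456, 3486 and 1703 calls in the 4 classes.

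The replicate block raised endothelial-like calls from 29 to 131 and ended none of the named calls there. Elsewhere the numbers did not pair the libraries (same-number correlations of -0.0868, -0.0889 and 0.0273 in macrophage/monocyte-like, 0.0664, -0.0421 and -0.0402 in fibroblast/tenocyte-like, -0.168, -0.105 and -0.00211 in myogenic-like and 0.0651, -0.0739 and -0.0632 in all cells), and not every library correlated best with its own number. There the block gave 191 calls (473 without it), 2877 (3520), 981 (1602) and 5734 (6105), and 19 (54) in dendritic-like cells. Of the 39 named macrophage/monocyte-like genes that passed, 14 no longer did with the block.

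Library totals only shifted the median log2 fold by -0.15 in endothelial-like and -0.14 in myogenic-like cells, and the share of calls that were higher from 39.96% to 24.5% in macrophage/monocyte-like, 47.5% to 31.01% in fibroblast/tenocyte-like and 50.1% to 24.9% in myogenic-like cells.

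Shares tested by edgeR on cell numbers passed in endothelial-like (log2 -2.88, adjusted p = 0.0447), mural-like (-3.11, 0.0447) and adipocyte-like cells (5.61, 0.00195). Differences in points reversed for macrophage/monocyte-like cells with both libraries left out (4.76), dendritic-like cells with each library clustered on its own (-0.227), myogenic-like cells at resolution 0.5 (-0.113) and 2 (-0.281) and myofibre-like cells in named clusters (0.153). Ranges without each library were 0.383 to 3.31 (adipocyte), -0.173 to 3.89 (dendritic), -12.5 to -6.18 (endothelial), 17.2 to 29.3 (fibroblast/tenocyte), -1.14 to -0.186 (glial), -11.98 to 0.0564 (macrophage/monocyte), -4.08 to -1.89 (mural), -0.973 to 1.04 (myofibre) and -0.236 to 3.88 (myogenic), and -0.0352 to 10.4 for endothelial-like cells with mesenchymal transcripts.

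Reversed log2 folds in endothelial-like cells were, for Acta2, 0.10 (500 genes and 1000 UMIs), 0.38 (no doublets removed), 0.34 (resolution 2), 2.21 (each library on its own), 0.41 (both left out), 0.80 (no mural markers), range without each library -1.48 to 0.081. Pecam1 gave -0.34 (each library on its own), -0.017 (library totals) and -0.0020 (thinned), Col3a1 -0.065 (library totals, range -0.18 to 0.38) and Tgfb1 0.13 (thinned, range -0.44 to 0.0030). The range for Tagln was -0.67 to 0.46. With each library clustered on its own Cygb was 0.30, C1s1 0.43, Snai1 -0.13, Vwf -0.19, Pdgfrb 0.22, Ltbp1 0.58 and the angiogenic sprouting list -0.36.

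In macrophage/monocyte-like cells Mrc1 gave -0.028 (each library on its own), -0.0022 (limma-voom), -0.33 (both left out), range -0.21 to 0.48, and Gpnmb -0.0014 (replicate block), range -0.27 to 0.40. In the tenocyte-led cluster Fabp5 was -0.21, Ccl2 -2.13, Col1a1 0.12 and the leukocyte adhesion list -0.49. In myogenic-like cells Mymk gave -0.32 (500 genes and 1000 UMIs), -0.10 (resolution 2), -0.061 (library totals), -0.0023 (both left out), range -0.15 to 0.27. Myh3 gave -0.14 (500 genes and 1000 UMIs), -0.11 (resolution 2), Myod1 0.077 (resolution 2), 0.24 (each library on its own), range -0.26 to 0.13, and Cd74 0.0042 (each library on its own). The range for Myog was -0.48 to 0.026.

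Depth limits the endothelial-like results: 298 CLL cells were kept, and of them 224 reached 1000 UMIs.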

Other observations

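The tests of sterol synthesis genes and of imprinted genes, and that of free Tomato RNA, were chosen only after the values had been seen.

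MHC class II presentation genes ranked lower in fibroblast/tenocyte-like and myogenic-like cells as well as in macrophage/monocyte-like cells. The median was -1.73 in fibroblast/tenocyte-like cells, with 4 of 7 fallen (adjusted p = 0.40 with an estimated correlation), and -2.24 in myogenic-like cells, with 5 of 6 fallen (adjusted p = 0.21 with an estimated correlation). Macrophage/monocyte markers carried by these cells fell as well, from 484 to 215 CPM in fibroblast/tenocyte-like cells (11 of 13 fallen) and from 319.99 to 127 CPM in myogenic-like cells (7 of 12). The myogenic-like fold of Cd74 was -2.57, and 0.0042 with each library clustered on its own. In endothelial-like cells the list did not pass (median 0.31, camera adjusted p = 0.267, adjusted p = 0.76 with an estimated correlation). Oxidative phosphorylation genes ranked higher in fibroblast/tenocyte-like cells (median 0.21, 11 of 34 risen, adjusted p = 0.44 with an estimated correlation). In myogenic-like cells 4 of 34 rose (median 0.18, adjusted p = 0.54 with an estimated correlation). Dissociation and immediate early genes ranked lower in myogenic-like cells (median -0.41, adjusted p = 0.21 with an estimated correlation), with 11 of 24 fallen and 2 risen. They ranked higher in endothelial-like cells (median 0.30, adjusted p = 0.36 with an estimated correlation), with none past edgeR. Resident-type macrophage genes ranked lower in fibroblast/tenocyte-like cells (median -1.18, adjusted p = 0.40 with an estimated correlation), where macrophage markers were lower as well.

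Fdps, an enzyme gene of sterol synthesis, rose in macrophage/monocyte-like, fibroblast/tenocyte-like and myogenic-like cells, which prompted a list of the pathway's enzymes, tested without Fdps. It ranked higher in all 3 classes (largest camera adjusted p = 3.81e-04), but did not pass (adjusted p = 0.25, 0.17 and 0.13 with an estimated correlation). Of its 18 tested members 6, 15 and 5 rose, with medians of 0.66, 0.96 and 0.50. In endothelial-like cells the list did not pass camera (adjusted p = 0.39, 0 of 12 risen, median 0.15). A rise of sterol synthesis shared by those 3 classes is a hypothesis that these data may hold but do not settle.

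Igf2, Dlk1 and Zim1, imprinted genes, fell in fibroblast/tenocyte-like cells, which prompted a list of imprinted genes, tested without the 5 that prompted it. It ranked lower in fibroblast/tenocyte-like and myogenic-like cells (largest camera adjusted p = 3.81e-04), and did not pass (adjusted p = 0.17 in both with an estimated correlation). Of its tested members 10 of 19 and 7 of 16 fell, with medians of -0.49 and -0.30, while in all cells summed 3 rose and 4 fell. In macrophage/monocyte-like cells it ranked lower too (median -0.75, camera adjusted p = 3.24e-04, 2 of 14 fallen) and did not pass (adjusted p = 0.48 with an estimated correlation). In endothelial-like cells it did not pass camera (adjusted p = 0.97, 0 of 13 fallen). A fall of imprinted genes shared by classes may be present and was not settled. RNA carried from fibroblast/tenocyte-like cells, and the make-up of that class, were not set apart from such a fall. Dlk1 was among the genes leading the Pi16 cluster, on average 2.58% of that class in CLL and 14.9% in SHAM. The groups overlapped in that cluster's share.

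Tomato UMIs outside endothelial-like cells could come from free RNA or from reporter-bearing cells that changed type. With cells drawn down to 1000 UMIs, 5.31 ± 0.247% of fibroblast/tenocyte-like cells in CLL and 7.47 ± 3.37% in SHAM had one. In no library did that share lie above the upper 95% limit of the macrophage/monocyte-like share. Free Tomato RNA from endothelial-like cells as the whole source is argued against: at the share of endothelial RNA that endothelial markers allow, it would give at most 38.00% of the fibroblast/tenocyte-like Tomato level in any library and 28.2% of the macrophage/monocyte-like one. A low reporter background in all cells, which would also give like shares in both classes, was not tested. In myogenic-like cells the shares were 6.50 ± 1.74% and 14.04 ± 1.84% (two-sided exact permutation p = 0.10, the smallest possible), and Tomato levels were 74.98 ± 7.65 and 134 ± 34.3 CPM. The myogenic-like share lay above that limit in all 3 SHAM libraries and in no CLL library, and the dendritic-like share (10.9 ± 5.04% and 14.1 ± 0.728%) in 3 SHAM and 2 CLL libraries. The macrophage/monocyte-like level is thus no common background for all classes, and where the myogenic-like and dendritic-like UMIs came from was not tested. Over all barcodes Tomato was at 67.4 ± 3.28 CPM in CLL and 282 ± 83.3 CPM in SHAM (exact p = 0.10).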
